A study of Mus musculus with 6 samples.

How the data were processed

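RNA from the kidneys of 6 mouse embryos at E13.5, 3 of them Fat4-/- and 3 Fat4+/+, was sequenced as 1 library per embryo. The labels describe total RNA extracted with TRIzol from both kidneys of an embryo, with most of the ureter taken off, and embryos from 1 pregnant female. The embryos are separate animals, so the p-values measure the spread between animals of a single litter. The labels number the embryos 1 to 3 in each genotype and do not say that embryos of the same number belong together. In the column headers, however, the wildtype and mutant embryo of each number carry consecutive library names.

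The authors deposited 1 table of the whole series, with an Ensembl gene identifier, a gene name and 1 column per library. Per the file headers the reads were trimmed, and the deposited unit is RPKM in a corrected form named cRPKM; how the correction was made is not given in the sources used here. The submitters' processing notes name Bowtie and mm9, with versions not given in the sources used here. The table has 22667 genes, of which 1114 hold no value in it and 21553 do; 2818 are at 0 in every library. Each column was matched to its sample by the header text in that sample's description, and all 6 columns were used.

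Because these values are not counts, a count model was not used. Values were tested as log2(cRPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend, 2-sided, genotype as the single term), for the 12315 genes with a mean of at least 1 cRPKM over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method, with calls at 0.05. A log2 fold change is the mutant minus the wildtype mean on the log2(cRPKM + 1) scale, which understates the change of low genes. Ratios and means ± SD are of cRPKM. An exact permutation test of a single gene with 3 embryos against 3 cannot go below p = 0.1, so single genes rest on the model fitted across all genes. Values of genes with near-identical copies, such as histone, ribosomal protein and globin genes, are uncertain, as the handling of shared reads is not given in the sources used here; the same holds for antisense and overlapping genes.

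The 33 gene lists were nephron progenitors, early nephron, podocytes, tubule maturation, ureteric bud tip, ureteric epithelium, cortical stroma, medullary stroma and smooth muscle, endothelium, the Fat and Dachsous family, macrophages, erythroid cells, nerve and neural crest, adrenal cortex, gonad and germ cells, skeletal muscle, liver, Y-linked genes, Yap and Taz targets, Wnt and beta-catenin targets, Ret, Fgf and Erk targets, the Notch pathway, Bmp and Smad targets, the retinoic acid pathway, planar cell polarity, cell cycle, p53 targets, hypoxia and glycolysis, immediate early and heat shock genes, extracellular matrix, ribosomal proteins, histones and the mitochondrial respiratory chain. Some genes stand in more than 1 list. The 31 lists with at least 3 tested members were compared with all other tested genes by limma's camera with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists. With the preset correlation 12 lists passed, 5 up and 7 down; with the estimated correlation none did, with 2 at an unadjusted p under 0.05 and a lowest adjusted p of 0.458. Members were also counted after adjustment over all genes and over the list alone. Dchs2 and Xist have no values used here. Results of a few single genes are not reported here.

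The named genes were Fat4 and its tested family members, 13 key markers, the 12 called genes with the largest rise and the 12 with the largest fall besides Fat4 whose mutant and wildtype values did not overlap, and up to 3 members of each list by smallest unadjusted p. Members that passed after adjustment over their list alone, members too low to test, and matrix, stromal and muscle genes given per library were named after their values were seen. This rule, the gene lists, the test, its filter, the 20 Mb window around Fat4 and all alternatives but 2 were fixed before the data were examined.

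Gene positions came from GENCODE mouse release M21 on GRCm38, joined by Ensembl identifier; 12133 tested genes had one, and these positions differ from those of mm9 to which the values refer. Called and other genes within 20 Mb of Fat4 and elsewhere were compared by Fisher's exact test, with a 95% interval.

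Read totals are unknown. Relative depth was estimated from genes at 0 in some library and under 3 cRPKM in all, where a value is a small number of reads times the value of 1 read. For each library the factor between it and wildtype embryo 1 was taken that explained the most ratios of values of at least 0.2 cRPKM by 1 to 3 reads on each side, within 1.5%. The depths relative to wildtype embryo 1 were 0.952 (17 of 30 genes explained), 0.904 (17 of 35), 1.00 (23 of 34), 1.03 (22 of 32) and 1.04 (17 of 28) for wildtype embryos 2 and 3 and mutant embryos 1, 2 and 3. The search covered only factors near 1, so a large gap in depth between the genotypes could not have been found. No interval could be given for single values.

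Alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 cRPKM, quantile normalisation, scaling by the median ratio, eBayes without trend and with robust estimation, library weights, the embryo number as a block, the mean log2 of 4 Y-linked genes as a covariate, each library left out in turn, windows of 10 and 40 Mb, and counting genes whose values do not overlap. Chosen after seeing the data were a correction for GC content and a fit without genes within 40 Mb of Fat4. Where a left-out library leaves 2 in a group, the spread is pooled over both groups.

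The test was checked on simulated data with 200 changed genes among 12315. It recovered 70.4% of genes changed by 0.3 on the log2 scale and 100% of those changed by 0.5 or by 1. Of the calls 6.12% were false, and no gene was called with no change simulated. With 1 list shifted, 1 of 30 other lists was called. The simulated genes varied independently of each other, so the check does not cover false calls of lists whose genes vary together. It also held no uneven sex and drew the changed genes at random, so the recovered shares do not hold for genes that vary more. In the real data Penk, at a log2 fold change of -0.77 with an SE of 0.152, was not called. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.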

Results

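The 6 libraries were made from kidneys of 6 mouse embryos collected at E13.5, a stage at which the ureteric bud branches into mesenchyme that holds nephron progenitors and stroma. In the first group 3 embryos were homozygous for a Fat4 mutation (Fat4-/-), in the second 3 were wildtype (Fat4+/+), and the 2 kidneys of an embryo went into 1 library. Expression was given per gene as cRPKM, a corrected form of reads per kilobase scaled to the mapped reads of the library. Genes above 0 numbered 17705, 17578 and 17620 in the wildtype libraries and 17541, 17485 and 17501 in the mutant libraries. The cRPKM of a library summed to between 473695 and 503223. Read totals are unknown. In a search limited to factors near 1, the steps between low values put the depth of the other 5 libraries at 0.904 to 1.04 times that of wildtype embryo 1. Pearson correlations between libraries ran from 0.991 to 0.996 over 15 pairs, taken across genes, which are not independent replicates. No pair shared the same value at more than 0.739% of the tested genes. The first principal component held 39.9% of the variance, with scores of -9.10, -2.45 and -8.99 in the wildtype libraries and 0.416, 11.3 and 8.86 in the mutant libraries.

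The comparison of mutant with wildtype kidneys addresses how loss of Fat4, a giant atypical cadherin that binds Dachsous cadherins, changes gene expression in a kidney whose nephron progenitor pool it is thought to restrict. Fat4 itself (ENSMUSG00000046743, chromosome 3, 38886940 to 39011985, GRCm38) was at 16.74, 15.69 and 16.83 cRPKM in the wildtype libraries and at 7.82, 7.20 and 7.49 in the mutant libraries. Its mean fell from 16.4 ± 0.634 to 7.50 ± 0.310 cRPKM (SD, n = 3), or 45.7% of wildtype (log2 fold change -1.03, SE 0.0476, adjusted p = 0.000155). This level separated the libraries by their genotype labels but did not by itself show that both copies were mutated. The part of the gene that the mutation removes was not given in the sources used here. Eya1, a gene of nephron progenitors, rose from 34.4 ± 1.41 to 47.2 ± 0.681 cRPKM (SD, n = 3), and Osr1, another, from 20.8 ± 1.83 to 27.9 ± 1.19 cRPKM. Hnf4a, a nuclear receptor of the proximal tubule, fell from 2.42 ± 1.20 to 0.430 ± 0.164 cRPKM (SD, n = 3). Pdgfra, a growth factor receptor of stromal and other mesenchymal cells, fell from 41.9 ± 2.08 to 29.8 ± 0.584 cRPKM (SD, n = 3).

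**Figure D1:**
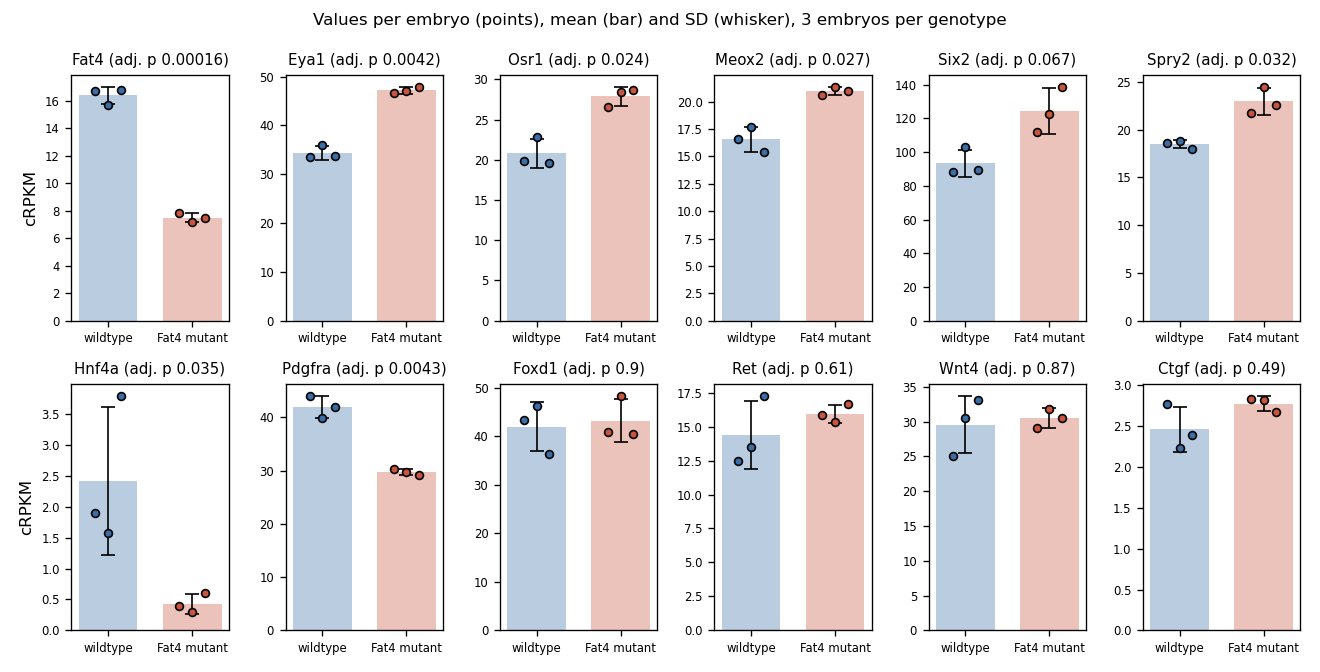
Expression of 12 genes in cRPKM (y axes, from 0) in 3 wildtype and 3 Fat4 mutant kidney libraries; bars are means, whiskers SD and points single embryos. Fat4 falls to 45.7% of wildtype, Eya1, Osr1, Meox2 and Spry2 lie higher in every mutant than in every wildtype embryo, and Hnf4a and Pdgfra lie lower.

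In all, 68 genes were higher and 108 lower in mutant kidneys among 12315 tested (limma, adjusted p under 0.05), and 626 and 981 had an unadjusted p under 0.05. The changes were small, with a median absolute log2 fold change of 0.41 over the called genes. The ratio of mean cRPKM reached 1.5 for 11 of the higher and 45 of the lower genes. All 176 called genes had mutant values that did not overlap the wildtype values, as did 2245 of the tested genes (18.2%, against 10% by chance for 3 against 3). The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were expressed in the 3 wildtype libraries and in mutant embryo 1 and were near 0 in mutant embryos 2 and 3, so that sex was uneven between the genotypes. With the score of these genes as a covariate, 1 gene was called higher (Kcnmb2) and 1 lower (Fat4). The other calls ended, and standard errors widened from a median of 0.0594 to 0.0846 over the called genes. Residual degrees of freedom went from 4 to 3. The median fold was 0.943 of that without the covariate. All 175 called genes besides Fat4 kept their sign and an unadjusted p under 0.05. With the covariate, the genotype term in effect compared mutant embryo 1 with the wildtype libraries. These genes were called with that embryo included, so their kept sign and size were largely set by the choice of genes. The kept folds are thus no evidence against an effect of sex. With 1 library left out there were 71 calls without wildtype embryo 1, 128 without wildtype embryo 2 (41 of them higher), 34 without mutant embryo 1, 24 without mutant embryo 2 and 30 without mutant embryo 3.

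Of 19 tested members of the nephron progenitor list, 3 rose, none fell and 16 did not pass over all genes, and 9 rose and none fell adjusted over the list alone. Eya1, a transcriptional cofactor needed to form the metanephric mesenchyme, lies on chromosome 1 (14168954 to 14310235) and had a log2 fold change of 0.45 (SE 0.0415, adjusted p = 0.00418). Osr1, a zinc finger factor of intermediate mesoderm and progenitors, was at 0.41 (SE 0.0632, adjusted p = 0.0237) and the homeobox gene Meox2 at 0.33 (SE 0.0525, adjusted p = 0.0268). Six2, Meox1, Itga8, Uncx, Robo2 and Spock2 rose adjusted over the list alone. Six2, which keeps progenitors undifferentiated, was at 88.16, 102.74 and 89.18 cRPKM in wildtype and 112.05, 122.64 and 138.91 in mutant libraries (log2 fold change 0.41, adjusted p = 0.0673 over all genes). Cited1 (0.09, adjusted p = 0.614) and Gdnf, the ligand of Ret (0.15, adjusted p = 0.324), did not pass. The list had a median log2 fold change of 0.20 and lay above the other genes (camera adjusted p = 1.22e-09; adjusted p = 0.458 with an estimated correlation). Eya1 passed without each library in turn (adjusted p at most 0.0257). Osr1 and Meox2 lost their calls without wildtype embryo 1 or any 1 mutant embryo (adjusted p up to 0.0983 and 0.111).

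In the early nephron list, which covers renal vesicles and their derivatives, 2 of 18 tested members fell and none rose over all genes. Adjusted over the list alone, 5 fell and none rose (Dll1, Dkk1, Papss2, Cdh6 and Osr2). Dkk1, a secreted Wnt inhibitor, went from 9.51 ± 0.626 to 6.71 ± 0.762 cRPKM (SD, n = 3, log2 fold change -0.45, adjusted p = 0.0332). Papss2, an enzyme that makes the sulfate donor, went from 6.41 ± 0.493 to 4.66 ± 0.381 cRPKM (SD, n = 3, log2 fold change -0.39, adjusted p = 0.0367). Wnt4, the signal that starts epithelial conversion, and Pax8 did not pass (0.05 and -0.03, adjusted p = 0.870 and 0.932). The list had a median of -0.25 and lay below the other genes (camera adjusted p = 1.02e-05; adjusted p = 0.531 with an estimated correlation). Wildtype embryo 3 stood apart, with the mean level of the members 0.17 above the wildtype mean on the log2 scale, against -0.14 and -0.04 in the other wildtype and -0.32, -0.29 and -0.14 in the mutant libraries. Without that library camera gave an adjusted p of 0.00176. Dkk1 lost its call without wildtype embryos 2 or 3 or mutant embryos 1 or 2 (adjusted p up to 0.123), and Papss2 without each of the 6 libraries (up to 0.129).

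Of the podocyte list, none of 5 tested members passed over all genes, and 3 fell adjusted over the list alone, among them Synpo and Podxl. Its median was -0.27 (camera adjusted p = 0.00558; adjusted p = 0.531 with an estimated correlation), with a camera adjusted p of 0.0365 without wildtype embryo 3. In the tubule maturation list 3 of 12 members were high enough to test, of which 1 fell over all genes and 3 fell adjusted over the list alone. Hnf4a, on chromosome 2 (163506808 to 163572910), had a log2 fold change of -1.21 (SE 0.210, adjusted p = 0.0352). The endocytic receptor Lrp2 was at -0.33 (adjusted p = 0.186 over all genes) and the water channel Aqp1 at -0.28 (adjusted p = 0.247). That list had a median of -0.33 (camera adjusted p = 0.00176; adjusted p = 0.458 with an estimated correlation). Of 17 members of the early nephron, podocyte and tubule lists too low to test, the mutant mean was lower for 14 and higher for 3 (Umod, Magi2 and Col4a3). Among those lower, Irx1 averaged 1.18 in wildtype and 0.263 cRPKM in mutant libraries, Irx2 0.687 and 0.107, and the podocyte gene Nphs1 0.180 and 0.00667. Wildtype embryo 3 stood apart from the other wildtype libraries for these genes, with Hnf4a at 3.79 cRPKM against 1.90 and 1.57, and Nphs1 at 0.350 against 0.110 and 0.0800. The share of all genes too low to test with a lower mutant mean was not counted, so the 14 of 17 has no base rate. Genes at 1 cRPKM or more numbered 12257 to 12282 in mutant and 12315 to 12408 in wildtype libraries. Hnf4a lost its call without wildtype embryo 1 or any 1 mutant embryo (adjusted p up to 0.133) and was under the expression minimum without wildtype embryo 3. Synpo and Aqp1 passed without wildtype embryo 2 (0.0207 and 0.0416).

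**Figure D2:**
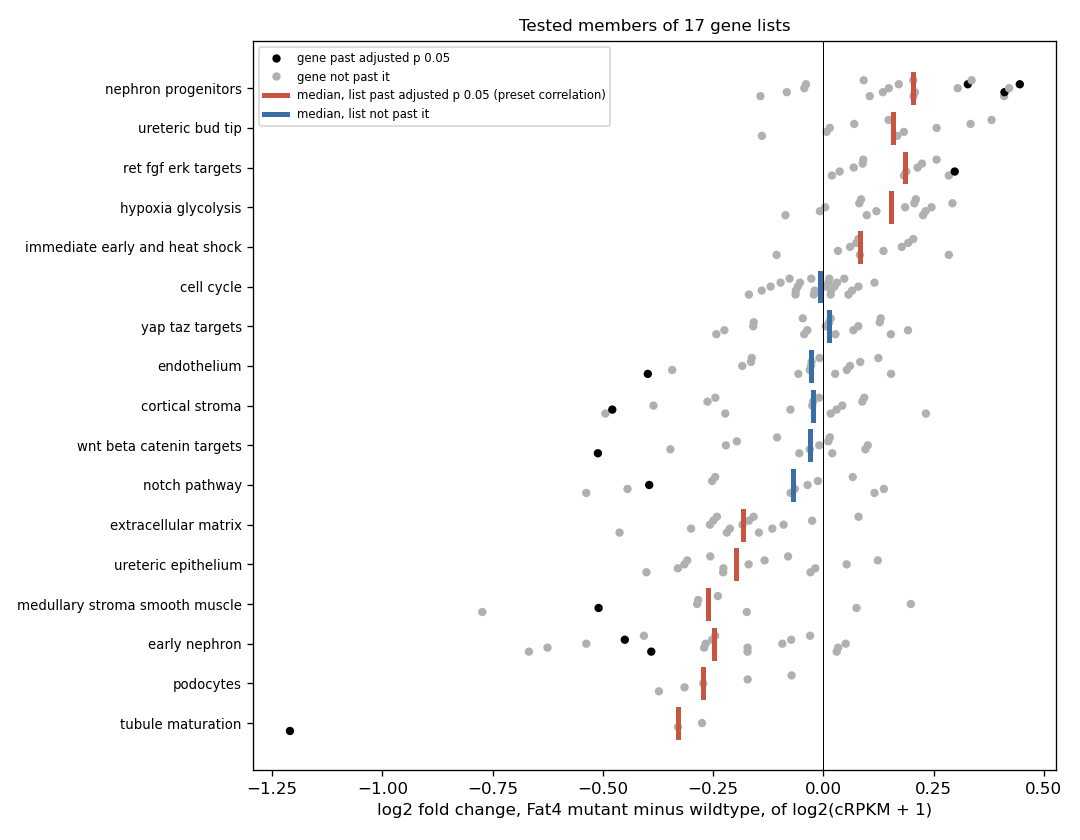
Log2 fold change (x axis, mutant minus wildtype, of log2(cRPKM + 1)) of each tested member of 17 gene lists. Black points passed an adjusted p of 0.05 over all genes, grey points did not, vertical bars are medians (orange where the list was called with the preset correlation, blue where it was not), and they run from -0.33 for tubule maturation to 0.20 for nephron progenitors.

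The ureteric lists moved in opposite directions, a difference that was not itself tested. For genes of the branching tip, none of 10 tested members passed over all genes, and 4 rose adjusted over the list alone, among them Etv4, Adamts18 and Gfra1. The median was 0.16 and the list lay above the other genes (camera adjusted p = 0.00107; adjusted p = 0.521 with an estimated correlation). Ret, the receptor that drives branching, and Wnt11, a signal made by the tip, did not pass (log2 fold changes 0.15 and 0.01, adjusted p = 0.609 and 0.975). For genes of the ureteric epithelium as a whole, none of 14 passed over all genes, and 9 fell adjusted over the list alone. They included Wnt7b, which signals to medullary stroma (log2 fold change -0.32, adjusted p = 0.110 over all genes), the cell adhesion gene Cdh1 (-0.40, adjusted p = 0.129) and the keratin gene Krt18 (-0.23, adjusted p = 0.127). The median was -0.20 (camera adjusted p = 0.000427; adjusted p = 0.586 with an estimated correlation). Wildtype embryo 3 again stood apart, with the mean level of the members 0.15 above the wildtype mean on the log2 scale, against -0.11 and -0.04 in the other wildtype and -0.18 to -0.16 in the mutant libraries. Without it the camera adjusted p was 0.0336. Wnt9b, which induces nephrons from the ureteric side, did not pass (-0.08, adjusted p = 0.680).

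Stromal genes divided. Pdgfra, on chromosome 5 (75152292 to 75198215), fell with a log2 fold change of -0.48 (SE 0.0453, adjusted p = 0.00427) and passed without each library in turn (adjusted p at most 0.0265). It was the 1 gene of 16 in the cortical stroma list to pass over all genes, while 1 rose (Fibin) and 4 fell adjusted over the list alone. The transcription factor genes Snai2 and Tcf21 were at -0.24 and -0.26 (adjusted p = 0.0536 and 0.0660 over all genes). Foxd1, the marker of stromal progenitors, was at 42.0 ± 5.04 and 43.2 ± 4.43 cRPKM (SD, n = 3, adjusted p = 0.901). The list did not pass (median -0.02, camera adjusted p = 0.154; adjusted p = 0.809 with an estimated correlation). With the preset correlation it passed downwards without wildtype embryo 3 (0.000483), with the Y-linked score as covariate (0.0342), with quantile normalisation (0.0312) and with library weights (0.0196). Its wildtype libraries lay apart, with mean levels of the members of 0.17, 0.02 and -0.19 around the wildtype mean on the log2 scale, against -0.13 to -0.09 in the mutant libraries. The proteoglycan gene Dcn was at 36.47 cRPKM in wildtype embryo 1 against 13.93 to 19.07 in the other 5 libraries. In the list for medullary stroma and smooth muscle, 1 of 8 tested members fell over all genes, the homeobox gene Alx1 (-0.51, SE 0.0609, adjusted p = 0.0117). Of that list, 1 rose (Tnc) and 3 fell adjusted over the list alone. Penk, an opioid precursor gene of medullary stroma, was at -0.77 (adjusted p = 0.0540 over all genes) and Wnt5a at -0.29 (adjusted p = 0.0590). The list lay below the other genes with a median of -0.26 (camera adjusted p = 0.00861; adjusted p = 0.458 with an estimated correlation), and did not pass with the embryo number as a block (0.0547). Alx1 lost its call without mutant embryo 2 or 3 (adjusted p up to 0.0571), and Penk passed without wildtype embryo 2 (0.00783).

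Matrix genes lay lower as a list, although none of 15 passed over all genes or adjusted over the list alone. Fn1, for fibronectin, was at -0.26 (adjusted p = 0.272) and Fbn1, for fibrillin, at -0.18 (adjusted p = 0.361). The median was -0.18 (camera adjusted p = 0.0142; adjusted p = 0.809 with an estimated correlation). Wildtype embryo 1 stood apart here, with the periostin gene Postn at 77.85 cRPKM against 34.95 to 49.51 in the other 5 libraries and the proteoglycan gene Lum at 15.18 against 4.62 to 7.49. The matrix list did not pass without wildtype embryo 1 (0.773), without mutant embryo 1 (0.102) or without a filter on low values (0.0537), and over its alternatives ran from 5.54e-06 to 0.773.

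Of 12 tested genes induced by Ret, Fgf and Erk signalling 1 rose over all genes, the feedback inhibitor Spry2 (18.5 ± 0.434 to 22.9 ± 1.41 cRPKM, SD, n = 3, log2 fold change 0.30, adjusted p = 0.0324). Adjusted over the list alone, 4 rose and none fell (Spry2, Dusp6, Etv4 and Egr1). All 12 had a fold change above 0, and the median was 0.19 (camera adjusted p = 2.26e-06; adjusted p = 0.458 with an estimated correlation). Spry2 lost its call without each of the 6 libraries in turn (adjusted p 0.0656 to 0.101). For hypoxia and glycolysis none of 14 passed over all genes, and 5 rose adjusted over the list alone (Slc2a1, Pdk1, Ldha, Pgk1 and Eno1). The median was 0.15 (camera adjusted p = 6.34e-05; adjusted p = 0.473 with an estimated correlation). Of immediate early and heat shock genes, which also respond to handling of tissue, none of 11 passed over all genes, and 2 rose adjusted over the list alone (Egr1 and Ier2). Their median was 0.08 (camera adjusted p = 0.000689; adjusted p = 0.458 with an estimated correlation). Etv4 and Etv5 stand in the Ret list and the ureteric tip list, and Egr1 in the Ret list and the immediate early list.

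Targets of the Hippo effectors Yap and Taz did not pass as a list (camera adjusted p = 0.639). None of 17 tested members passed over all genes, and 1 rose adjusted over the list alone (Amotl2, 0.19, adjusted p = 0.0664 over all genes). The median was 0.01 and the mean -0.01, with an upward test direction. Ctgf and Cyr61, matricellular genes widely read as Yap targets, did not pass. Ctgf was at 2.46 ± 0.277 and 2.78 ± 0.0929 cRPKM in wildtype and mutant libraries (SD, n = 3, adjusted p = 0.493), and Cyr61 at 9.67 ± 0.738 and 10.3 ± 0.728 (adjusted p = 0.682). In the Fat and Dachsous family Fat4 fell, both over all genes and adjusted over the list alone. The other 4 tested members did not pass (Dchs1 adjusted p = 0.609, Fat3 0.678, Fjx1 0.777, Fat1 0.798). The family list did not pass (0.610) and had a median of 0.05, a mean of -0.18 and a downward test direction.

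Of Wnt and beta-catenin targets 1 of 13 fell over all genes, the Wnt inhibitor Apcdd1 (log2 fold change -0.51, SE 0.0554, adjusted p = 0.00805). With Lgr5 and Nkd1, 3 fell adjusted over the list alone, while Axin2 was at 0.10 (adjusted p = 0.577). Of the Notch pathway 1 of 12 fell over all genes, the target Nrarp (-0.39, SE 0.0614, adjusted p = 0.0246). Here 1 rose (Hes1) and 3 fell (Nrarp, Hes5 and Dll1) adjusted over the list alone, and Dll1, Jag1 and Lfng are also in the early nephron list. Neither list passed (camera adjusted p = 0.114 for each). Bmp and Smad targets did not pass (0.123), with none of 8 past all genes and 2 fallen adjusted over the list alone (Id2 and Bambi). The retinoic acid pathway did not pass (0.154), with none of 11 past all genes and 1 fallen adjusted over the list alone (Rarb). Lists that passed downwards with 1 library left out were Wnt without wildtype embryo 1 (0.00236) or mutant embryo 3 (0.0433), Notch without wildtype embryo 1 (0.000820) or mutant embryo 3 (0.0154), and Bmp without wildtype embryo 1 (0.0350) or mutant embryo 2 (0.0436). Under other settings Notch passed downwards with the embryo number as a block (0.0477), with GC correction (0.0219) and without genes within 40 Mb of Fat4 (0.0275), and Wnt with GC correction (0.0408). Bmp passed downwards with library weights (0.0298), the Y-linked score (0.0342) and GC correction (0.0219). All these passes used the preset correlation, and the estimated one was run only in the main fit. There camera gave an adjusted p of 0.809 for Wnt and for Notch and 0.582 for Bmp. Apcdd1 passed without each library (adjusted p at most 0.0380). Nrarp lost its call without any 1 mutant embryo (up to 0.0983), and Hes5 passed without wildtype embryo 1 (0.0459).

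Genes of planar cell polarity, the cell cycle and the p53 response did not pass as lists (camera adjusted p = 0.910, 0.910 and 0.610). Of planar cell polarity genes none of 13 passed over all genes, and 1 fell adjusted over the list alone (Prickle2). Of cell cycle genes none of 24 passed by either adjustment, with 12 above and 12 below 0. Of p53 targets none of 9 passed over all genes, and 1 rose adjusted over the list alone (Phlda3). The p53 list had a median just below 0, a mean of 0.02 and an upward test direction.

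By the size of the change, the 12 largest falls besides Fat4 included those of the brush border enzymes Dpp4, Enpep and Ggt1, which had log2 fold changes of -0.86, -0.76 and -0.71 (adjusted p = 0.0196, 0.0196 and 0.0191). The sodium pump subunit Atp1b1 went from 20.1 ± 4.57 to 11.4 ± 0.517 cRPKM (SD, n = 3, log2 fold change -0.74, adjusted p = 0.0332). The ammonium transporter Rhcg went from 3.42 ± 0.212 to 1.65 ± 0.0351 cRPKM (SD, n = 3, -0.74, adjusted p = 0.00187). Besides Hnf4a the others were the carboxypeptidase Cpb2 (-0.98, adjusted p = 0.00691), Enpp2, which makes lysophosphatidic acid (-0.92, adjusted p = 0.00297), the surface antigen Ly6a (-0.96), Igfbp7 (-0.77), clusterin, Clu (-0.69), and D630042F21Rik (-1.01).

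The 12 largest rises were led by Kcnmb2, an accessory subunit of calcium-activated potassium channels (1.64 ± 0.0603 to 4.75 ± 0.278 cRPKM, SD, n = 3, log2 fold change 1.12, adjusted p = 0.000181). Gm14226 followed (1.07, adjusted p = 0.00122), then the glutathione peroxidase gene Gpx6 (0.59, adjusted p = 0.00465), Colq (0.58), Psd2 (0.55) and RP23-369M17.1 (0.53). Type II collagen, Col2a1, was at 0.51 (adjusted p = 0.00438), and the muscle intermediate filament gene Des went from 38.2 ± 2.46 to 54.2 ± 3.10 cRPKM (SD, n = 3, 0.49, adjusted p = 0.0119). The rest were 1110032F04Rik (0.50), the arginase gene Arg1 (0.49), Wnt6 (0.49) and Accn4 (0.47). Of the 36 called genes named by the rule besides Fat4, 10 kept their call without each library in turn: Eya1, Pdgfra, Apcdd1, Kcnmb2, Gm14226, Gpx6, Col2a1, Cpb2, Enpp2 and Rhcg. The other 26 lost it at least once. Among the largest rises and falls, adjusted p then reached 0.139 for Ly6a and 0.112 for D630042F21Rik without mutant embryo 2, 0.124 for Atp1b1 and 0.153 for Arg1 without mutant embryo 1, 0.145 for Accn4 and 0.123 for Wnt6 without mutant embryo 3, and 0.0883 for RP23-369M17.1 without wildtype embryo 1.

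Called genes were over-represented around Fat4 on chromosome 3. Within 20 Mb either side, 8 of 99 tested genes other than Fat4 were called, against 167 of 12033 elsewhere (odds ratio 6.24, 95% interval 2.58 to 13.1, Fisher's exact test, 2-sided, p = 8.95e-05). Neighbours that fell included Mccc1 (log2 fold change -0.65), Exosc9 (-0.65), Bbs7 (-0.61), Mecom (-0.29), Sclt1 (-0.29) and the cyclin gene Ccna2 (-0.21), and Kcnmb2 rose (1.12). None of the 12 tested genes within 2 Mb was called, the count from 0 to 5 Mb was 6 of 28, and from 5 to 40 Mb it was 4 of 130. The strain label gives 6 generations of backcrossing.

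**Figure D3:**
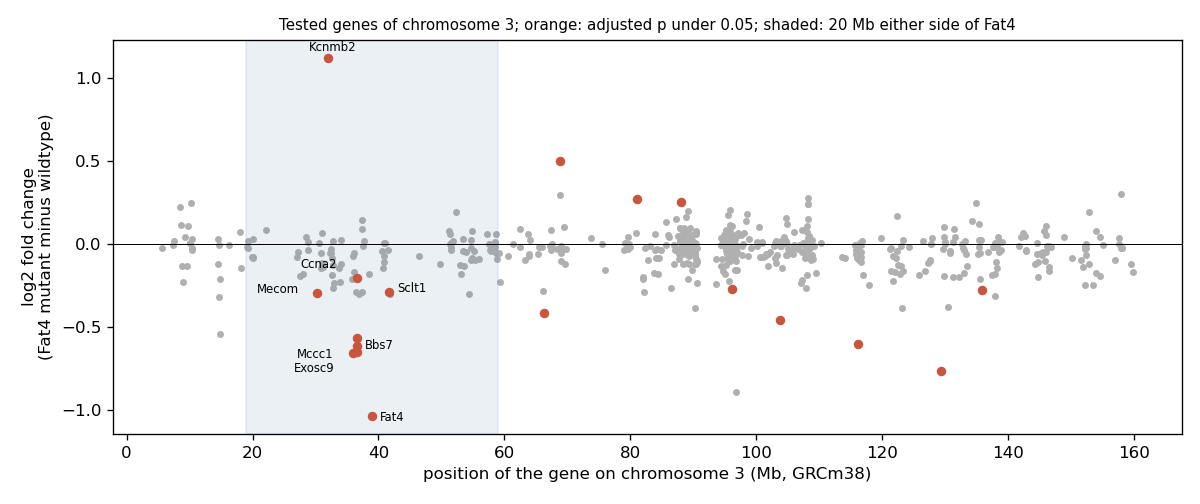
Log2 fold change (y axis, mutant minus wildtype, of log2(cRPKM + 1)) of tested genes along chromosome 3 by GRCm38 position in Mb (x axis), with the 20 Mb on either side of Fat4 shaded and called genes marked. The 8 called neighbours of Fat4 lie in the shaded part, with Kcnmb2 the highest point at 1.12.

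Markers of other cell types varied between libraries. In the endothelium list 1 of 16 fell over all genes, the tight junction gene Cldn5 (26.3 ± 2.12 to 19.7 ± 0.652 cRPKM, SD, n = 3, log2 fold change -0.40, adjusted p = 0.0229). With Tek and Emcn, 3 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.396). Of 5 tested nerve and neural crest genes 1 fell by either adjustment (over all genes and adjusted over the list alone), Gap43, a gene of growing axons (-0.50, SE 0.0821, adjusted p = 0.0298). That list did not pass (0.910), with a median of 0.03, a mean of -0.14 and a downward test direction. Tubb3, a neuronal tubulin gene, averaged 2.29 ± 1.98 cRPKM in wildtype libraries (SD, n = 3), with wildtype embryo 3 at 4.57. Cldn5 and Gap43 lost their calls without wildtype embryo 1 or any 1 mutant embryo (adjusted p up to 0.0901 and 0.115).

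Macrophage genes did not pass as a list (camera adjusted p = 0.753), with none of 10 past all genes and 1 fallen adjusted over the list alone (Mrc1). Erythroid genes did not pass (0.318), with none of 9 past either adjustment. Adrenal cortex genes did not pass (0.910), with none of 4 past all genes and 1 fallen adjusted over the list alone (Akr1b7), a median of 0.03, a mean of -0.05 and a downward test direction. Skeletal muscle genes did not pass (0.396), with none of 4 past either adjustment. Actc1, a striated muscle actin gene, was at 7.26 cRPKM in wildtype embryo 1 against 1.39 to 3.35 in the other 5 libraries. Gonad and liver lists had 2 tested members each and were not tested as lists. Cyp26b1 (also in the retinoic acid list) and Aard rose adjusted over the list alone for gonad, and no liver gene passed either adjustment. Macrophage genes passed upwards without wildtype embryo 1 (0.00236) and erythroid genes upwards without wildtype embryo 2 (0.000730), while Mrc1 and Akr1b7 passed without wildtype embryo 2 (0.0351 and 0.0435). The list passes used the preset correlation. With an estimated correlation and all libraries, camera gave an adjusted p of 0.975 for macrophage and 0.931 for erythroid genes.

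The 4 Y-linked genes fell adjusted over the list alone, and none passed over all genes. Their median log2 fold change was -2.78 (camera adjusted p = 0.00415; adjusted p = 0.531 with an estimated correlation). Ddx3y was at 24.64, 23.92 and 23.10 cRPKM in wildtype embryos, 24.59 in mutant embryo 1 and 0.03 and 0.05 in mutant embryos 2 and 3. Kdm5d, Eif2s3y and Uty passed without mutant embryo 1 (2.97e-07, 2.25e-06 and 1.04e-06). Ribosomal protein genes did not pass (0.553), with none of 75 past either adjustment, a median just above 0, a mean of -0.01 and an upward test direction. Histone genes did not pass (0.724), with none of 21 past either adjustment. Mitochondrial respiratory chain genes did not pass (0.910), with none of 82 past either adjustment, a median of -0.02, a mean of -0.01 and an upward test direction. The ribosomal and mitochondrial lists passed upwards without wildtype embryo 1 (0.00107 and 0.0464) or mutant embryo 3 (0.00174 and 0.0381) and downwards without wildtype embryo 3 (0.0107 and 0.0179). Without mutant embryo 2 the mitochondrial and histone lists passed downwards (0.00339 and 0.0372), as did histones with the Y-linked score as covariate (0.0342). These passes, too, used the preset correlation. With an estimated correlation and all libraries, camera gave an adjusted p of 0.975 for ribosomal and histone genes and 0.981 for mitochondrial genes.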

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

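All alternatives here were chosen before the values were seen, except the GC content correction and the fit without genes within 40 Mb of Fat4. Fat4 kept its call in all 18 alternatives (log2 fold change -1.12 to -0.98, adjusted p at most 0.0189), and the odds ratio of called genes near Fat4 stayed above 1 and past the test in all 19 that gave a finite one (4.78 to 28.1, exact p at most 0.00393); with the Y-linked score none was finite. Against 68 higher and 108 lower, the counts were 10 and 22 without a filter, where 18735 genes were tested, and 48 and 61 at a mean of at least 5 cRPKM, where 9592 were and 109 of the 114 called genes still tested passed. They were 109 and 164 with the embryo number as a block, 1 and 1 with the Y-linked score, and 890 and 1355 for values that do not overlap, where chance gives 10% of genes. With 1 library left out they were 7 to 53 and 17 to 87, from fewer samples, and the genes called with all libraries kept their sign wherever tested. The labels do not say whether embryos of the same number share a step of handling, but the column headers give them consecutive library names. A pairing thus stays open, and the main fit does not model it. Same-numbered embryos correlated at 0.0985, 0.205 and 0.277 in their deviations, and other pairs ran from -0.373 to 0.227. Mutant embryo 1 correlated better with wildtype embryo 3 and mutant embryo 2 with wildtype embryo 1. The block kept 156 of 176 calls and lowered the median standard error from 0.0541 to 0.0449. Residual degrees of freedom then went from 4 to 2. The medullary stroma list had an adjusted p of 0.0547 under the block and the matrix list 0.0537 without a filter; the causes were not tested. Of 11 called lists besides the Y-linked one, 9 kept their call with each library left out, the tubule list in the 5 such fits that could test it, and the matrix list ran from 5.54e-06 to 0.773. With an estimated correlation adjusted p was 0.458 for nephron progenitors, tubule maturation, medullary stroma, Ret targets and immediate early genes, 0.473 for hypoxia, 0.521 for ureteric tip, 0.531 for early nephron and podocytes, 0.586 for ureteric epithelium and 0.809 for matrix. Directions turned for the Y-linked list with its own score as covariate (0.739), for ribosomal (0.0107) and mitochondrial genes (0.0179) without wildtype embryo 3, and for mitochondrial genes without mutant embryo 2 (0.00339); with 1 library left out these lists ran from 0.00107 to 0.544 and 0.00339 to 0.490, and the causes were not tested. The first component held 39.9% of variance, 43.0% at a mean of at least 5 cRPKM and 41.4% to 46.8% with 1 library left out. Among 132 named genes, 37 called, calls were lost 77 times under other settings and 93 times with a library left out, never with a turned sign; 27 others gained a call in 44 cases and 9 uncalled lists in 25, and 79 uncalled gene or list results changed sign. The tubule list had fewer than 3 tested members without wildtype embryo 3, and lists were not run with robust estimation, which camera does not take. Depth limits low genes: most tubule and podocyte markers lay under 1 cRPKM and were not tested.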

Other observations

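The genes in the first 2 paragraphs were chosen after their values were seen, as were the tests of sex, of a strain segment, of a short-range effect and of the third wildtype library; the other tests were set before their result was seen. Thy1, a surface glycoprotein of mesenchymal cells, fell from 14.4 ± 0.227 to 9.67 ± 0.0872 cRPKM (SD, n = 3; log2 fold change -0.53, limma adjusted p = 0.00122), and the adhesion molecule Vcam1 from 8.95 ± 0.567 to 5.57 ± 0.0666 cRPKM (-0.60, adjusted p = 0.00297). Angpt1, the ligand of the endothelial receptor Tek (-0.54, adjusted p = 0.0191), Tshz3, a transcription factor needed for ureter smooth muscle (-0.40, adjusted p = 0.0117), and Gli1, a target and effector of hedgehog signalling (-0.31, adjusted p = 0.0196), also fell. Thy1 and Vcam1 passed without each library in turn (adjusted p at most 0.0126 and 0.0239). Angpt1 lost its call without mutant embryo 2 or 3 (up to 0.0759), Tshz3 without any 1 mutant embryo (up to 0.0594), and Gli1 without each library but wildtype embryo 3 (up to 0.0735).

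Among genes that rose were Bcl2l11, which promotes apoptosis (22.6 ± 0.842 to 29.6 ± 0.642 cRPKM, SD, n = 3; log2 fold change 0.38, limma adjusted p = 0.00805), and Rdh10, which makes retinaldehyde from retinol (29.8 ± 1.33 to 39.3 ± 2.26 cRPKM; 0.39, adjusted p = 0.0191). Rspo1, an amplifier of Wnt signalling (0.38, adjusted p = 0.0224), the forkhead gene Foxd2 (0.42, adjusted p = 0.0231) and Gas1, a hedgehog co-receptor (0.36, adjusted p = 0.0298), rose as well. Bcl2l11 passed without each library in turn (at most 0.0459). Rdh10 and Rspo1 lost their calls without any 1 mutant embryo (up to 0.0694 and 0.0816), Foxd2 without each library but wildtype embryo 3 (up to 0.0804), and Gas1 without each but wildtype embryo 2 (up to 0.115). With the Y-linked score as a covariate none of these 10 genes passed, with adjusted p from 0.0783 for Thy1 to 0.528 for Gas1 and log2 fold changes of -0.55 and 0.25 for the pair.

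The 176 calls between genotypes were set against the other ways to divide the libraries: 1 of 10 splits, the real one, gave as many, the highest other gave 1, and 10 splits are too few for a share under 0.05. For uneven sex, each wildtype library in turn was kept as the control of the 1 mutant with Y-linked expression, and the 100 genes with the smallest p between the other mutants and the other wildtype libraries were taken, Y-linked genes and Fat4 left out. Its shift was at the median 0.871, 0.528 and 0.870 of theirs with wildtype embryos 1, 2 and 3 as control, where sex alone would give about 0 (lowest and highest 0.594 and 0.934 for 50 genes, 0.517 and 0.841 for 200). Earlier ratios of 0.914 and 0.920 used the same wildtype libraries for both shifts and were replaced. Sex stays open, as these values rest on a single library, whose first component score (0.416) lay nearer wildtype embryo 2 (-2.45) than the other mutants (11.3 and 8.86), and all 3 wildtype libraries had Y-linked expression.

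Called genes near Fat4 may reflect a segment of another strain kept around the mutated gene through 6 generations of backcrossing, or a short-range effect of the mutation. From 5 to 40 Mb the odds ratio was 2.27 (95% interval 0.602 to 6.07, exact p = 0.109), which keeps both open: a long segment would raise it and a short-range effect would not. Calls lay from 0 to 5 Mb (6 of 28, odds ratio 19.2, exact p = 2.39e-06) and from 0 to 10 Mb (8 of 48, odds ratio 14.3, exact p = 3.7e-07). None of 12 genes lay both within 2 Mb and past the test. More calls within 2 Mb were the mark set for a short-range effect, but 12 genes are too few to decide (95% interval of the odds ratio 0 to 24.8). The window centred on Fat4 had 8.16% of its genes called, and 2 of 138 windows of the genome reached that, both overlapping it. A change of expression through loss of Fat4 protein was not tested for these genes, and sequence variants were not analysed here.

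Lower tubule genes may come from a delay of the whole embryo, from a smaller share of all nephron epithelium or from 1 wildtype library. The third wildtype library alone stays open: without it the median of the same 3 members kept 74.4% of its value (-0.33 to -0.25), but Hnf4a and Lrp2 then lay under the expression minimum and 1 member was left to test. For a delay, embryonic globins made up 45.0 ± 1.34% of globin values in mutant and 43.6 ± 2.07% in wildtype libraries (SD, n = 3), a difference of 1.38 points (exact permutation test, 2-sided, p = 0.4); the ranges overlapped, which had been set as evidence against it, but the difference lay in the direction of a delay and within the spread, so a small delay stays open. For a smaller share, the early nephron and podocyte medians (-0.25 and -0.27) were to lie within the interquartile range of the tubule members (-0.77 to -0.30) and did not, and the lower quartile of podocyte genes (-0.31) lay above the tubule median (-0.33) and so met the bound set against it; with 3 tubule members these margins are smaller than their spread, and the reading was left open after that was seen. The log2(cRPKM + 1) scale also understates low genes such as the tubule members. Lrp2, which gave the tubule median of -0.33, had a mutant to wildtype cRPKM ratio of 0.635. Podxl, which gave the podocyte quartile of -0.31, had a ratio of 0.791. Because of this scale, the comparison of medians and quartiles cannot judge a smaller share. Loss of Fat4 slowing tubule formation remains a further hypothesis, not told apart from these explanations here.

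If mutant kidneys held fewer or less mature proximal tubule cells, a second list of 18 proximal tubule genes, written after the first results and before its own values were looked at, might also lie lower. In the mutant the mean was lower for 16 of the 18, with wildtype embryo 3 the highest wildtype library for 13 (16 were lower without it too), but 7 were high enough to test, 6 of them below 0 and none called, with a median of -0.07 and a camera p of 0.133 (0.310 with an estimated correlation), so the list did not pass and the hypothesis stays open. The share of all low genes with a lower mutant mean was not counted, so the 16 of 18 has no base rate. For a weaker hedgehog response, prompted by Gli1, the list of other targets had 2 tested members and could not be tested as a list, and Ptch1 was at -0.18 (limma adjusted p = 0.406), not past the threshold.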
